A study of Mus musculus with 13 samples.

How the data were processed

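Gene expression was measured in quadriceps muscle of 13 male C57Bl/6 mice aged 4 months, 1 array per animal, on Affymetrix perfect-match strip arrays of the mouse genome. The groups were labelled SKM-KO (n = 3), C (n = 3), SKM-Tg (n = 4) and Wt (n = 3). The labels do not spell out the group names or say which control belongs to which group; C was taken as the control of SKM-KO and Wt as that of SKM-Tg from the naming and the design, and every comparison rests on this. SKM-KO was read as ablation and SKM-Tg as gain of function of DOR in skeletal muscle, because the study's design names both, and DOR is an earlier name of Trp53inp2. Per the labels, the mice ate standard chow, the muscles were frozen in liquid nitrogen, RNA was extracted with TRIzol and columns, and 25 ng of total RNA per sample was amplified isothermally and labelled with biotin.

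The deposited values are log2 signals of 45141 probe sets. The authors made them with RMA, which corrects background, normalizes arrays and summarises probes, and they give no software version. The values ran from 2.14 to 13.21, and the array medians lay between 4.85 and 4.94. No scan date, strip or batch is given, so no batch term was possible. An array has no read depth; the number of arrays per group limits the precision.

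Control probe sets (104) were set aside, and 28898 of the other 45037 probe sets had exactly 1 gene symbol in the annotation at hand. A further 551 had several symbols and 15588 had none here; both kinds were left out of the gene tests. Each gene took the value of its probe set with the highest mean over all arrays. Genes were tested where that mean reached 4.9, the median of the means of all non-control probe sets, which left 10411 of 17097 genes. Of these, 5546 had more than 1 probe set. The annotation was used for names alone, and no genomic positions are given.

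All 13 arrays were fitted together in limma 3.58.1 under R 4.3.3, with 1 mean per group and empirical Bayes moderation (9 residual and 3.62 prior degrees of freedom). The contrasts were SKM-KO minus C, SKM-Tg minus Wt, the difference of these effects, and Wt minus C. Tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the genes tested, and the threshold was an adjusted p of 0.05. Intervals are 95% intervals of the fit, and errors are standard errors (SE) of the fit unless marked SD, the standard deviation.

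Lists of genes for pathways and cell type markers, 36 in all, were tested with limma's camera at a preset inter-gene correlation of 0.01, with p-values adjusted over the lists. Camera asks whether the test statistics of a list's genes are on average higher or lower than those of the other genes. It was repeated with a correlation estimated from the data, and fry, which asks whether a list's genes move on balance in 1 direction, was run beside it. Of 786 list symbols, 634 were among the genes tested after 6 had been updated to current names. A lymphocyte list with 3 measured members fell below the minimum of 5 and was not tested. Each list also got a count of members past the threshold when adjusted over the list alone, with no adjustment over the lists.

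Named genes followed a rule. It took Trp53inp2 and its paralogue Trp53inp1, and for each comparison up to 12 genes per direction that passed the threshold, filled up with the smallest p-values. It also took up to 4 members of a list by p, the 10 smallest p-values of the difference of effects, and genes that passed in Wt minus C. The groups, contrasts, lists, naming rule and first set of alternatives were chosen before the data were examined.

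The fit was tested on simulated data in which 200 genes per run were shifted, over 5 runs. In SKM-KO minus C it found 42.1% of 1.5-fold, 81.2% of 2-fold and 97.6% of 3-fold changes, and 2.8% of its calls were false. In SKM-Tg minus Wt it found 55.8%, 85.7% and 96.7%, but 36.2% of its calls were false. Fitting only the groups compared found 20.6%, 63.0% and 84.5% there with 5.7% false calls. For SKM-KO minus C that separate fit found 68.1%, 93.1% and 98.5% with 5.0% false calls. All 5 shifted lists were found and 0 unshifted lists were called by camera, on genes simulated as independent. After the results were seen, 200 sets of arrays with no change in any group were drawn from the residuals of each line. This keeps its spread and the correlation of genes as far as so few residuals hold them. These sets show how many lists camera calls by chance at the preset correlation, and how far SKM-KO minus C and Wt minus C agree through the C arrays they share. A list whose genes happened to vary little in those residuals can hardly be called in any set. With 3 C arrays, the controls could not be split into parts of at least 2 arrays each.

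The alternatives were median centring, quantile and cyclic loess normalization, no filter and a filter at the 75th percentile, the mean of a gene's probe sets, calls over all probe sets, eBayes with trend and robust, array quality weights, a separate fit, other list tests, and each array left out in turn. The array weights used limma's gene-by-gene method, because the REML method did not converge. A covariate for the signal of GC-rich control probes, leaving out both arrays with the highest such signal, and a block for mice of C and SKM-KO with neighbouring numbers were chosen after seeing the data. This signal is the mean of 11 nonspecific control probe sets with GC counts from 15 to 25. Permutation tests used SciPy 1.17.1 and figures matplotlib 3.10.9 under Python 3.11.15.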

Results

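Log2 signals were compared for 10411 genes in quadriceps muscle of 13 mice. Ablation of DOR, now named Trp53inp2, was examined in SKM-KO (n = 3) against C (n = 3). The arrays labelled SKM-Tg (n = 4), which stand for gain of function in the design, were compared with Wt (n = 3). Trp53inp2 encodes a regulator of autophagosome formation that also acts as a coactivator of nuclear receptors. The design asks how each manipulation alters gene expression in skeletal muscle. Each line was compared with the group taken as its control, and the array medians of 4.85 to 4.94 lay close together.

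Trp53inp2 fell by 2.35 on the log2 scale in SKM-KO (SE 0.14, limma adjusted p 3.76e-06), a change of 5.08-fold. Its 1 probe set gave a mean of 8.79 ± 0.21 (SD, n = 3) in SKM-KO and 11.13 ± 0.06 (SD, n = 3) in C, and all SKM-KO arrays lay below all C arrays. In SKM-Tg the signal was 11.17 ± 0.11 (SD, n = 4), against 11.22 ± 0.23 (SD, n = 3) in Wt. That difference was -0.06 (95% interval -0.33 to 0.22, adjusted p 0.886), so no rise was detected. The limit of 0.22 holds for this fit alone, which pools the spread of all groups. Without Wt 2 the difference was 0.06, so a rise somewhat above 0.22 is not ruled out. The position of this probe set relative to the transgene and to the deleted exons is not given, so its signal in SKM-Tg is no check of that label. The paralogue Trp53inp1, a p53-induced partner of the autophagy machinery, has 2 probe sets. They differed by 0.45 and 0.27 between SKM-KO and C and by 0.51 and 0.31 between SKM-Tg and Wt, none past the threshold. With single arrays left out, the brighter probe set ran from 0.25 to 0.75 in SKM-KO minus C and from 0.076 to 0.88 in SKM-Tg minus Wt.

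**Figure D1:**
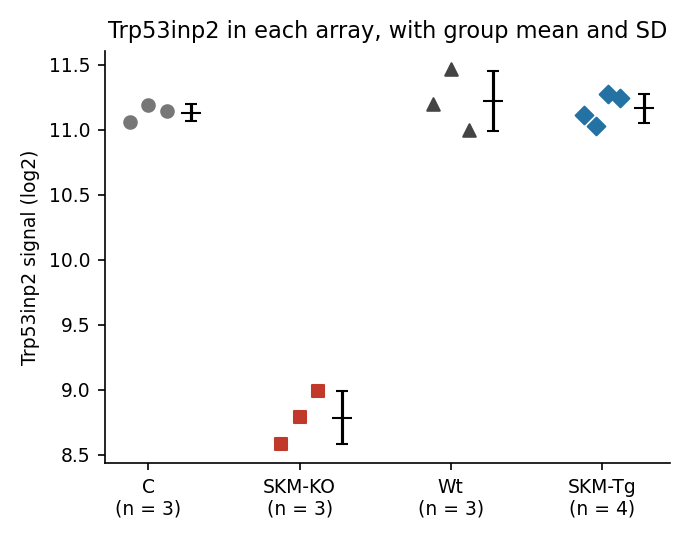
Log2 signal of Trp53inp2 in each of the 13 arrays (dots) by group, with the group mean and SD. The 3 SKM-KO arrays lie between 8.58 and 8.99, below all others, and SKM-Tg overlaps Wt.

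Trp53inp2 was the 1 gene that changed in SKM-KO minus C; 0 genes rose past limma's threshold, and 58 genes (0.56%) had an unadjusted p under 0.05. That number was 285 in a separate fit of SKM-KO and C, whose spread is the smaller, and 587 with array quality weights. Counted over all probe sets, 3 passed, among them a pair of Wdfy1, a gene chosen after its values were seen, which was also higher in Wt than in C. The other genes named have the smallest p-values, and none of them passed. On the higher side were Dkk3, a secreted glycoprotein of the Dickkopf family, at 0.83 (SE 0.20), and Gpm6b, a proteolipid family protein of neurons and glia, at 0.51 (SE 0.14). Fkbp5, a co-chaperone of the glucocorticoid receptor, stood at 0.53 (SE 0.20), and the potassium channel Kcna1 at 0.36. The ubiquitin pathway genes Usp29, Ube4a and Fbxl4 stood at 0.37, 0.35 and 0.31, and the myosin light chain Myl10 at 0.37. The signals of Usp29 lay near the filter. Atp13a5, Zfp128, Slc12a9 and Lysmd3 had values of 0.44, 0.38, 0.25 and 0.28.

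On the lower side were Hoxd8, a homeobox transcription factor, at -0.86 (SE 0.25), Tmem100 at -0.83 and Lancl1 at -0.45. H3c11, a replication-dependent histone H3, differed by -0.32 (SE 0.09), with Pigr at -0.32. Rfxap also stood at -0.32, but its probe sets differ in direction. Plasma proteins made mainly by the liver formed the rest: Alb at -2.23 (SE 0.82), Apoa1 at -1.03 (SE 0.32), Apoc3 at -0.80, Ttr at -0.76 and Apoa2 at -0.75. Alb ranged widely within C, with signals of 7.22, 8.67 and 5.37, against 5.33, 4.72 and 4.53 in SKM-KO. Of the 24 genes the rule named, 7 had several probe sets past the filter, and for 6 of them these had the same sign. Besides Trp53inp2, 11 of the 12 genes on the higher side were also positive in Wt minus C and 9 of the 11 on the lower side negative. Both comparisons subtract the same C arrays, and simulated arrays with no change in any group gave medians of 12 of 12 and 11 of 11, so the shared arrays alone give such agreement. At least as far from 0 there were 5 on the higher side, Dkk3 at 0.86, Fkbp5 at 0.60, Myl10 at 0.47, Zfp128 at 0.46 and Ube4a at 0.43, and 1 on the lower, Tmem100 at -1.18. With no change, 31 of 200 simulations gave as many on the higher side and 89 on the lower. Gpm6b stood at 0.08, Slc12a9 at 0.01 and Lysmd3 at 0.02, and Fbxl4 at -0.06, H3c11 at 0.09 and Lancl1 at 0.31 had the opposite sign.

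**Figure D2:**
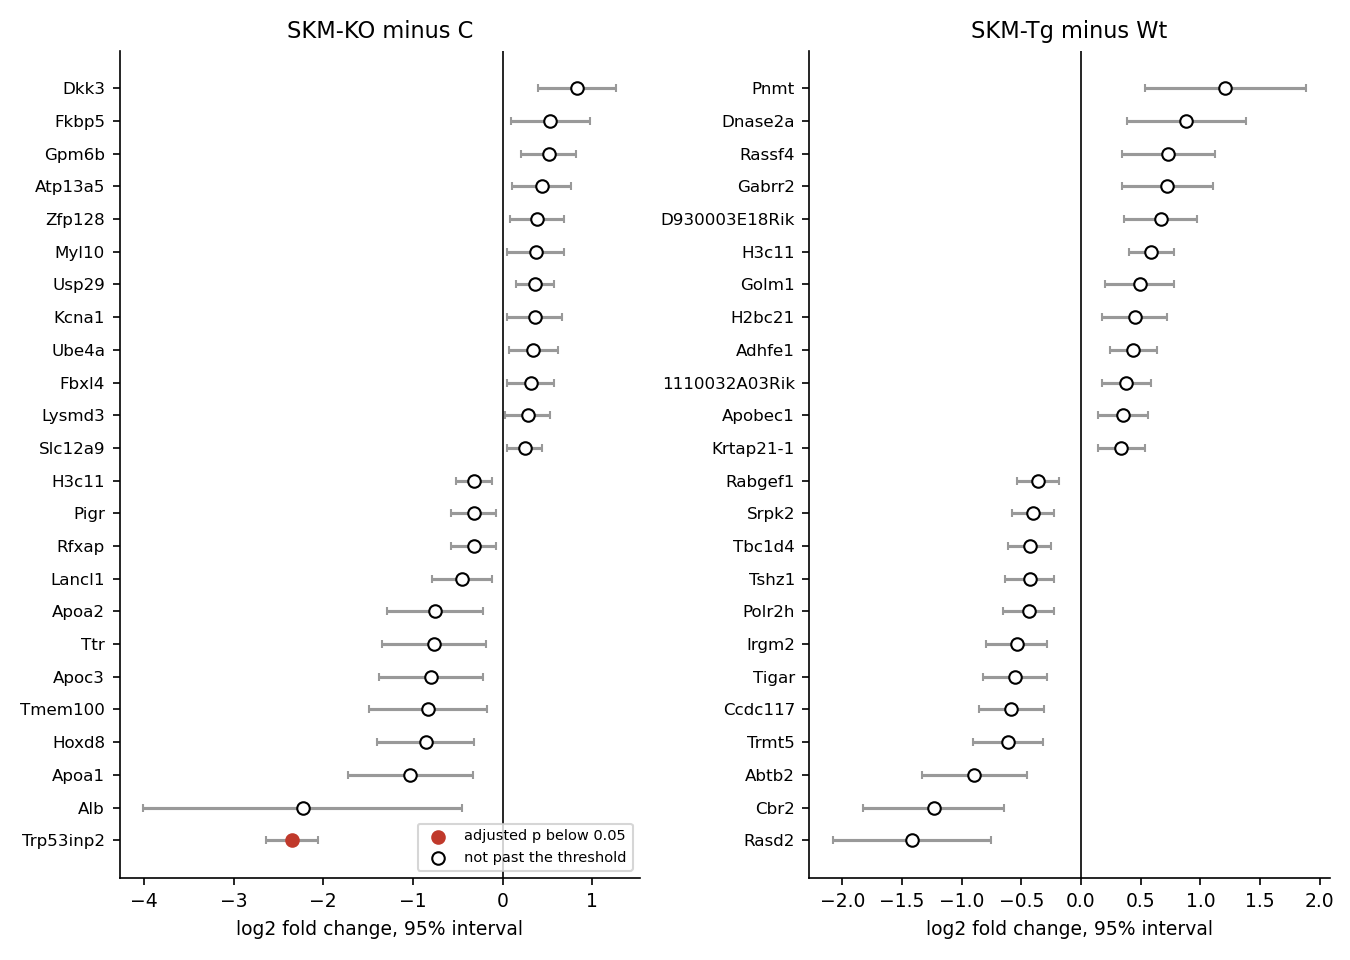
Log2 fold changes of the 24 genes named in each comparison, with 95% intervals; filled points have a limma adjusted p under 0.05. Only Trp53inp2 in SKM-KO minus C is filled.

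As groups, 7 of 35 gene lists passed camera in SKM-KO minus C, 6 higher and 1 lower, while the 9 other splits of the same 6 arrays called from 5 to 13. Markers of nerve and Schwann cells rose (6 of 6 measured members positive, median log2 change 0.24, adjusted p 1.33e-05; adjusted p 0.656 with an estimated correlation). Their members included the myelin genes Mbp at 0.58, Mal at 0.34 and Pmp22 at 0.33, and the Schwann cell regulator Sox10 at 0.16. Glucocorticoid targets were higher (16 of 16 positive, median 0.19, adjusted p 3.25e-05; adjusted p 0.656 with an estimated correlation), with Fkbp5 at 0.53, the cell cycle inhibitor Cdkn1a at 0.38, the metallothionein Mt1 at 0.37 and Errfi1 at 0.24. Without C 1 that call was lost (camera adjusted p 0.447), with Mt1 at -0.0021 and Errfi1 at -0.0057. In 54 of 200 simulations with no change the list's adjusted p was as small.

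Lysosomal genes rose (24 of 28 positive, median 0.09, adjusted p 0.00151; adjusted p 0.656 with an estimated correlation), with the cholesterol exporters Npc1 at 0.23 and Npc2 at 0.16, the cathepsin Ctsz at 0.17 and the acid lipase Lipa at 0.13. Atrophy genes also rose (19 of 24 positive, median 0.08, adjusted p 0.00151; adjusted p 0.656 with an estimated correlation). Among them were the stress-induced Sesn1 at 0.49, Cdkn1a at 0.38, the muscle ubiquitin ligase Trim63 at 0.21 and the transcription factor Foxo3 at 0.22.

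Genes of fatty acid oxidation and PPAR targets rose (23 of 26 positive, median 0.04, adjusted p 0.0368; adjusted p 0.827 with an estimated correlation), among them the lipid droplet proteins Plin5 at 0.23 and Plin2 at 0.18, the thioesterase Acot1 at 0.37 and the dehydrogenase Acadl at 0.11. Adipoq, a marker of fat cells, was 8.20 in SKM-KO 2 and 4.49 to 5.56 in the other arrays of this line. Macrophage markers rose (11 of 14 positive, median 0.16, adjusted p 0.0368; adjusted p 0.827 with an estimated correlation; adjusted p 0.959 with the direction turned without C 3), with the scavenger receptor Cd163 at 0.29, the Fc receptor Fcgr3 at 0.26, and Tyrobp and Cd68 at 0.20 each. Genes of glycolysis and glycogen fell (18 of 23 negative, median -0.04, adjusted p 0.0384; adjusted p 0.827 with an estimated correlation). Fbp2, the muscle fructose bisphosphatase, stood at -0.54, the glycerol phosphate dehydrogenase Gpd1 at -0.21, the phosphorylase kinase subunit Phkg1 at -0.11 and the mutase Pgam2 at -0.08. This call was lost with quantile normalization, no filter, array weights and a separate fit (adjusted p 0.0904, 0.113, 0.220 and 0.0637).

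Wt minus C subtracts the same C arrays, so that agreement with it is no separate evidence. Positive there were 6 of 6 members of the nerve list, 15 of 16 of the glucocorticoid, 21 of 28 of the lysosome, 17 of 24 of the atrophy, 13 of 26 of the oxidation, 11 of 14 of the macrophage and 16 of 23 of the glycolysis list. In simulated arrays with no change, where a list was called in the same direction, the medians were 4.5 of 6 for nerve, 12 of 16 for glucocorticoid, 15 of 24 for atrophy, 14 of 26 for oxidation, 8 of 14 for macrophage and 11 of 23 for glycolysis; the lysosome list was called in 0 of 200, so it has no such value. Of the 7 lists the glucocorticoid list alone passed in Wt minus C (adjusted p 0.0248; adjusted p 0.963 with an estimated correlation).

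The simulated arrays, which keep the correlation of genes seen in the few residuals, gave a median of 8 lists called in SKM-KO minus C (5th to 95th percentile 5 to 15), and 142 of 200 gave at least 7. An adjusted p as small was reached in 0 of 200 by the lysosome list, 6 by nerve, 40 by atrophy, 43 by oxidation, 54 by glucocorticoid, 56 by glycolysis and 86 by macrophage. The 0 of 200 does not set the lysosome list apart from chance, because all draws reuse the same few residuals. No call of these 7 lists held with an estimated correlation. Fry called 0 of 35 lists, and camera had 11 at an unadjusted p under 0.05. Without C 1 the glucocorticoid, atrophy, oxidation and glycolysis lists lost their calls (adjusted p 0.447, 0.214, 0.560 and 0.334), and without C 3 the macrophage list turned its direction (adjusted p 0.959). Without SKM-KO 1 the nerve list lost its call (adjusted p 0.0833), with the atrophy, oxidation, glycolysis and macrophage lists (0.0577, 0.206, 0.179 and 0.0720), and without SKM-KO 3 the last 3 did (0.0673, 0.413 and 0.239). In each of the 7 lists, 0 members passed over all genes and 0 when adjusted over the list alone. Autophagy genes did not pass (25 of 34 positive, median 0.07, adjusted p 0.0927). The members with the smallest p-values were the lipid kinase Pik3c3 at 0.16, Trp53inp1 at 0.45, the mitophagy receptor Bnip3 at 0.13 and Atg5 at 0.11. Fat cell markers did not pass either (4 of 6 positive, adjusted p 0.671). Retn stood at 0.43, Car3 at -0.08, Adipoq at 0.58 (SE 0.99) and Scd1 at 0.51, and without SKM-KO 2 Adipoq was -0.61 and Scd1 -0.66.

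In SKM-Tg minus Wt, limma called 0 genes, while 717 (6.89%) had an unadjusted p under 0.05, 156 higher and 561 lower. That number was 297 in a separate fit of SKM-Tg and Wt, 3447 with array quality weights, 3204 without Wt 3, 1280 without SKM-Tg 3 and 405 without SKM-Tg 1. On simulated data 36.2% of the calls of the joint fit were false in this comparison. The smallest adjusted p was 0.135, for H3c11, a replication-dependent histone H3 with a dim signal, at 0.59 (SE 0.09); all 4 SKM-Tg arrays lay above all Wt arrays. Without Wt 3 limma called 30 genes, and with array quality weights 1487. Other genes on the higher side, none past the threshold, were Pnmt, which converts noradrenaline to adrenaline, at 1.21 (SE 0.31), and the lysosomal nuclease Dnase2a at 0.88. The GABA receptor subunit Gabrr2 stood at 0.72, Rassf4 at 0.73, Golm1 at 0.49, H2bc21, another histone, at 0.45, and the mitochondrial enzyme Adhfe1 at 0.44. D930003E18Rik, 1110032A03Rik, Krtap21-1 and Apobec1 had values of 0.67, 0.38, 0.34 and 0.35.

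On the lower side was Tbc1d4, the Rab GTPase-activating protein that insulin signalling acts on to release glucose transporters, at -0.43 (SE 0.08, adjusted p 0.527). It passed when adjusted over the list alone, with no adjustment over the 35 lists, the 1 member of the insulin list to do so (p 0.00533). Others, not past the threshold, were the small GTPase Rasd2 at -1.42 (SE 0.31), the carbonyl reductase Cbr2 at -1.23 (SE 0.27), Abtb2 at -0.89, the tRNA methyltransferase Trmt5 at -0.61 and the fructose bisphosphatase Tigar at -0.55. Irgm2, an interferon-inducible GTPase, stood at -0.54, the splicing kinase Srpk2 at -0.40 and the RNA polymerase subunit Polr2h at -0.44. Ccdc117, Tshz1 and Rabgef1 had values of -0.58, -0.43 and -0.36. Of these 24 genes, 9 had several probe sets past the filter, and in all 9 these had the same sign.

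Of 35 lists, 1 passed camera in SKM-Tg minus Wt. Lysosomal genes fell (25 of 28 negative, median -0.18, adjusted p 0.0368; adjusted p 0.942 with an estimated correlation). Markers of other cell types, none of which passed, had lower medians: macrophage -0.27 (13 of 14 negative, adjusted p 0.302), fibroblast and matrix -0.27 (14 of 16, adjusted p 0.135) and endothelium -0.22 (10 of 12, adjusted p 0.288). The lysosomal genes included acid ceramidase, Asah1, at -0.35, the proton pump subunits Atp6v0d1 at -0.34 and Atp6v1b2 at -0.29, and cathepsin Ctsd at -0.18. In that list 0 members passed over all genes and 0 when adjusted over the list alone. Simulated arrays with no change gave a median of 2 lists called, 142 of 200 gave at least 1, and the lysosome list reached as small an adjusted p in 4 of 200. Fry called 0 of 35, and camera had 6 at an unadjusted p under 0.05. The call was lost without Wt 1, Wt 3, SKM-Tg 1 or SKM-Tg 3 (adjusted p 0.0749, 0.209, 0.0795 and 0.0598).

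The next lists by p did not pass. For the unfolded protein response, 17 of 19 members were negative (median -0.17, adjusted p 0.0661), with the transcription factor Xbp1 at -0.67, the chaperone Calr at -0.40, Manf at -0.35 and Herpud1 at -0.26. For immediate early genes, 18 of 20 were negative (median -0.31, adjusted p 0.0849), with Nr4a3 at -0.73, Fos at -0.82, Fosl2 at -0.52 and Jund at -0.46. For fat cell markers, 5 of 6 were positive (median 0.46, adjusted p 0.0894), with the adipokines Adipoq at 1.81 (SE 0.92) and Retn at 0.86, the desaturase Scd1 at 1.27 and the hormone-sensitive lipase Lipe at -0.14. For autophagy genes, 21 of 34 were negative (median -0.04, adjusted p 0.819), although camera's direction was up. Bnip3l stood at 0.33, Becn1 at 0.26, Atg13 at -0.37 and Atg5 at -0.23. Camera's direction was up and the median negative also for the glucocorticoid, atrophy, oxidation, p53, thyroid, oxidative stress, citric acid cycle and mitochondrial translation lists, none of which passed, while the median of all genes was -0.05; the insulin list had a positive median and a negative mean. In SKM-KO minus C the reverse held for the integrated stress, clock, oxidative stress and neuromuscular junction lists, which did not pass. Among smooth muscle markers Acta2, at -0.54, passed when adjusted over the list alone (p 0.0339, with no adjustment over the lists) and not over all genes.

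**Figure D3:**
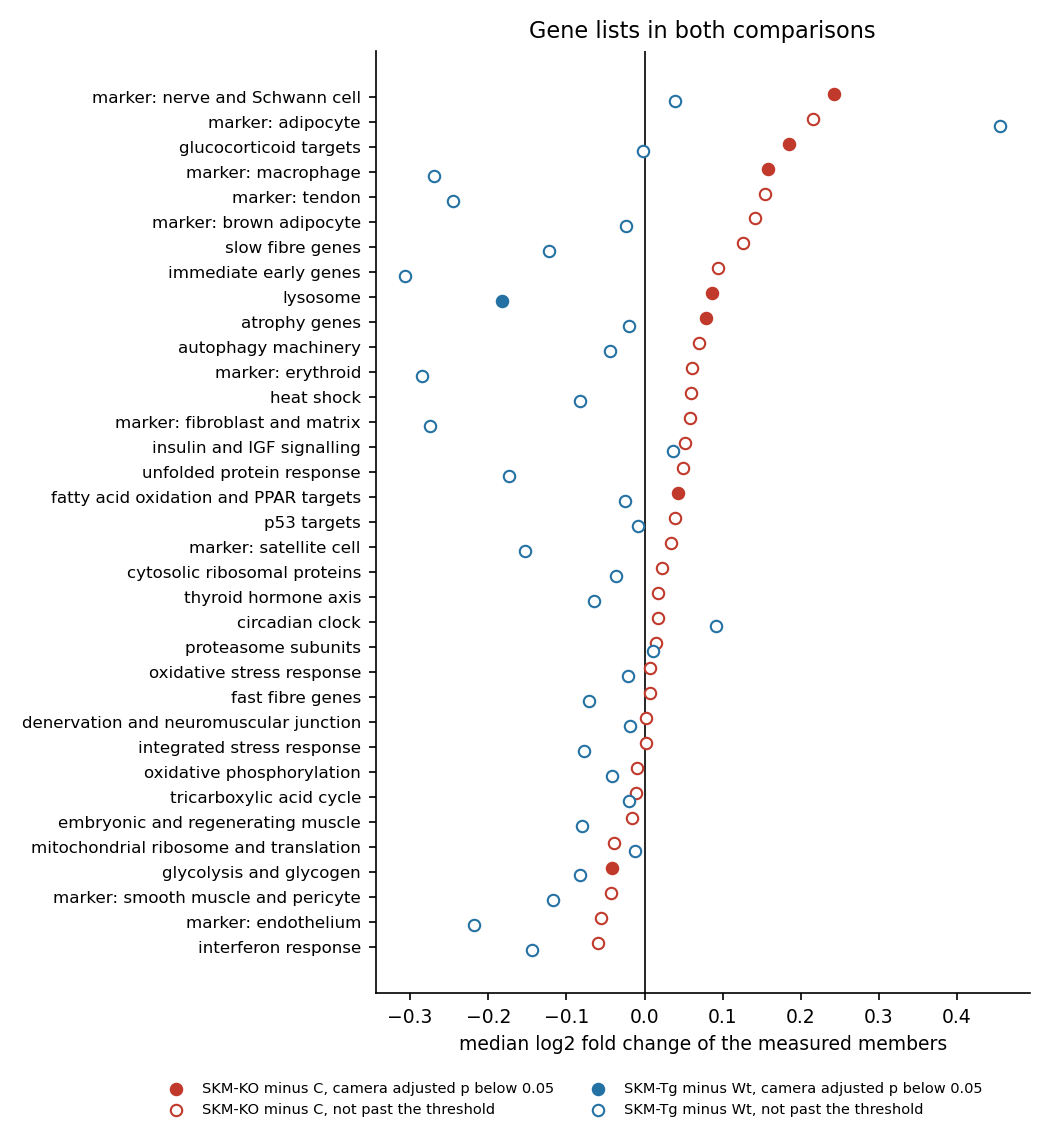
Median log2 fold change of each of 35 gene lists in SKM-KO minus C and in SKM-Tg minus Wt; filled points have a camera adjusted p under 0.05 at the preset correlation. The lysosome list is filled in both, at 0.09 in SKM-KO and -0.18 in SKM-Tg.

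The effects in SKM-Tg and in SKM-KO were then compared directly. The test of their difference called 2 genes: Trp53inp2 at 2.29 (SE 0.19, adjusted p 2.16e-04) and H3c11 at 0.91 (SE 0.13, adjusted p 0.0401). H3c11 was -0.32 in SKM-KO and 0.59 in SKM-Tg, each against its own controls. Its call was lost without each array in turn, with adjusted p-values from 0.0547 without Wt 3 to 0.25 without SKM-KO 3. Without Wt 3, Cbr2 passed in its place (-1.98, adjusted p 0.0167). Genes next in order, not past the threshold, were Dkk3 at -1.62 (adjusted p 0.219), Cbr2 at -1.56, Atp13a5 at -0.84, Ccdc117 at -0.79, Tbc1d4 at -0.60, Pnck at -0.58, Trp53bp1 at -0.52 and Wls at -0.51.

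Among lists, lysosomal genes had the smallest p for a difference of the effects (26 of 28 lower in SKM-Tg than in SKM-KO, median -0.29, adjusted p 2.62e-04; adjusted p 0.877 with an estimated correlation), with Asah1 at -0.46, Npc1 at -0.44, and Ctsz and Npc2 at -0.34 each. Genes of the unfolded protein response differed in the same direction (17 of 19, median -0.24, adjusted p 0.0146; adjusted p 0.877 with an estimated correlation), with Xbp1 at -0.67, Calr at -0.49, Dnajb9 at -0.38 and Atf6 at -0.27. So did immediate early genes (17 of 20, median -0.43, adjusted p 0.0347; adjusted p 0.877 with an estimated correlation), with Nr4a3 at -1.04, Fosl2 at -0.80, Ccn2 at -0.60 and Jund at -0.54. The call of the immediate early list was lost with 5 other settings, among them the GC-rich control signal as a covariate (adjusted p 0.481) and array weights (adjusted p 0.690). In all 3 lists 0 members passed over all genes or when adjusted over the list alone. Simulated arrays with no change gave a median of 5 lists called, 146 of 200 gave at least 3, and as small an adjusted p was reached in 0 of 200 by the lysosome, 29 by the unfolded protein response and 27 by the immediate early list. Because these arrays reuse few residuals, the 0 of 200 does not exclude chance for the lysosome list. Macrophage markers (13 of 14 negative, median -0.34) and fibroblast and matrix markers (15 of 16 negative, median -0.37) had adjusted p-values of 0.0697 each and did not pass. Across genes, which are not independent replicates, the effects had a Pearson r of -0.0163 and a Spearman rho of -0.0595, and 5458 genes (52.4%) had opposite signs.

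The control groups, which carry neither manipulation, were compared as a background. Wt minus C called 1 gene, Rab4a, a GTPase of endosome recycling, which was 1.06 higher in Wt (SE 0.14, adjusted p 0.0460), with means of 8.37 in C, 8.68 in SKM-KO, 9.43 in Wt and 9.23 in SKM-Tg. An unadjusted p under 0.05 was reached by 2891 genes (27.8%), a number that was 976 without Wt 2, 5249 without Wt 3 and 654 with the GC-rich control signal as a covariate. Glucocorticoid targets were higher in Wt (15 of 16, median 0.56, adjusted p 0.0248; adjusted p 0.963 with an estimated correlation). When adjusted over the list alone 7 rose, and Mt1 stood at 1.05, Cdkn1a at 0.81, Per1 at 0.80 and Cebpb at 0.61. The list lost its call without C 1 (adjusted p 0.182) and without Wt 3 (adjusted p 0.321), and in 60 of 200 simulations with no change its adjusted p was as small. Rab4a lost its call without each array other than Wt 3, with adjusted p-values up to 0.296 without C 2.

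Arrays of the Tg line stood further apart than those of the KO line. The median SD within groups was 0.222 in the Tg line and 0.108 in the KO line. The first principal component held 62.3% of the variance; Wt 2 stood at 55.6, SKM-Tg 3 at 25.2, Wt 1 at 17.4, SKM-Tg 4 at 11.2 and SKM-Tg 2 at 5.84, while SKM-Tg 1 stood at -7.68, Wt 3 at -12.7 and the KO line between -17.1 and -13.8. The signal of GC-rich control probes was 5.71 in Wt 2, 5.02 in SKM-Tg 3 and 4.74 in Wt 1, and 4.21 to 4.49 in the other arrays, 4.32 in SKM-Tg 4 among them. Adipoq was 7.66, 9.84, 8.12 and 8.52 in SKM-Tg and 6.31, 8.75 and 5.12 in Wt, with means of 8.53 and 6.73. A two-sided exact permutation test over 35 splits gave p 0.229 (adjusted 0.457 over 4 measures), and the smallest p it allows is 0.0571, so it could not have passed.

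**Figure D4:**
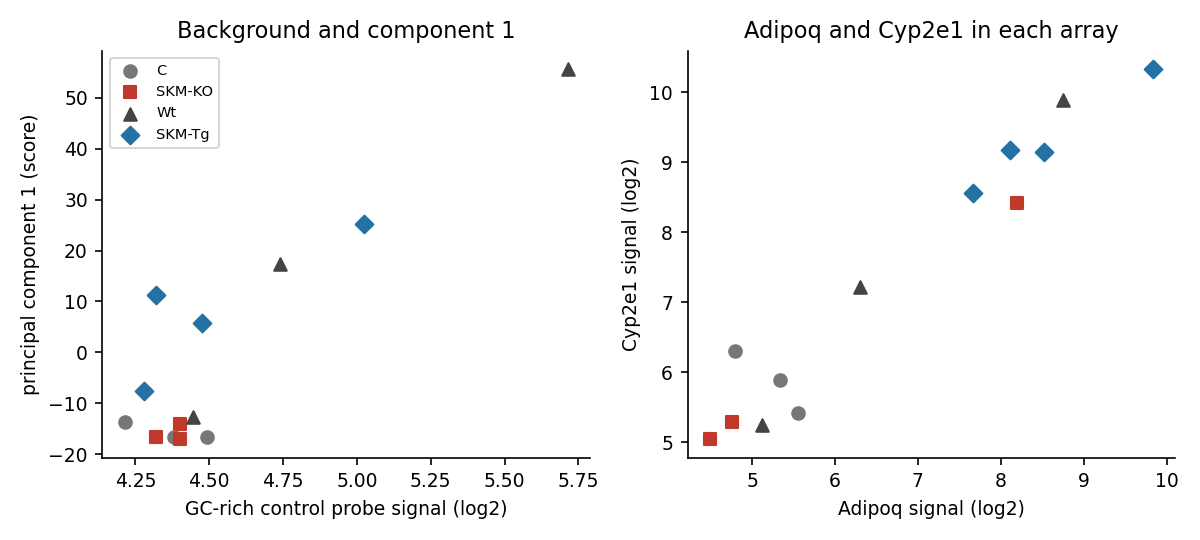
Left, signal of GC-rich control probes (log2) against principal component 1 for the 13 arrays by group, with Wt 2 at 5.71 and 55.6. Right, Cyp2e1, expressed in liver and fat, against Adipoq (log2); SKM-KO 2 lies at 8.20 on the Adipoq axis and the other arrays of its line at 4.49 to 5.56.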

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

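All tests of explanations and of other splits of the arrays were chosen after the results they address were seen; the tests of the difference of effects were not.

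Some effects differed between the lines by a test of the difference itself. For Trp53inp2 the effect in SKM-Tg minus the effect in SKM-KO was 2.29 (SE 0.19), and for H3c11 it was 0.91 (SE 0.13). The median differences were -0.29 for the lysosome list, -0.24 for the unfolded protein response list and -0.43 for the immediate early list. With an estimated correlation each had a camera adjusted p of 0.877, and fry called 0 of 35 lists, so these calls rest on camera's preset correlation. Simulated arrays with no change gave at least 3 lists in 146 of 200. As small an adjusted p was reached there in 0 of 200 by the lysosome list, 29 by the unfolded protein response list and 27 by the immediate early list. The simulated arrays reuse few residuals, so chance is not excluded for the lysosome list either. The real grouping called 2 genes and the highest of the other splits 1, so that 1 of 100 splits drawn, the real one included, gave as many. That speaks against chance only for a count with the ablated gene in it, and it leaves H3c11 undecided. The count is Trp53inp2, the ablated gene, and H3c11, whose call was lost without each array in turn (adjusted p 0.0547 to 0.25), and with 1 gene the count equals the highest of the other splits. The Pearson r of the effects across genes, -0.0163, is not told apart from chance: 82 of 100 splits gave one as far from 0, and the farthest other was -0.292.

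In SKM-KO minus C the real grouping called 1 gene and the highest of the other splits 0; 1 of 10 splits gave as many, and 10 splits are too few for a share under 0.05. For its 7 lists the other splits called from 5 to 13, with 9 of 10 splits as large, the real one included. Other groupings of these arrays thus mostly called as many lists. Simulated arrays with no change gave a median of 8, so the number of lists is no larger than chance gives. In SKM-Tg minus Wt limma called 0 genes, with 717 at an unadjusted p under 0.05; every split gives at least 0, so 35 of 35 gave as many by construction, and the count of splits says nothing about chance here. The split that set Wt 1, Wt 2 and SKM-Tg 3 against the rest called 3268 genes, and the one that set Wt 3, SKM-Tg 1 and SKM-Tg 2 against the rest 2303, which points to a structure of these arrays other than the groups. For the 1 list of that comparison, 29 of 35 splits called as many and the highest 8, so chance cannot be excluded. In Wt minus C the real grouping called 1 gene and the highest other split 0, with 1 of 10 splits as large, too few for a share under 0.05.

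Wdfy1, which encodes an endosomal protein that binds phosphoinositides, was lower in the C arrays than in all others by 3 of its 4 probe sets. A signal in probe sets that the gene tests do not use drew attention to it, and the gene was chosen after its values were seen. In SKM-KO minus C a pair of its probe sets rose by 1.31 (adjusted p 0.0245 over 22519 probe sets) and 1.36 (adjusted p 0.0251). In Wt minus C they rose by 1.67 (adjusted p 0.00354) and 1.52 (adjusted p 0.0113). Its brightest probe set, the one used for the gene, differed by 0.18 in SKM-KO minus C, with no call. There SKM-Tg 1, at 7.10, lay below all C arrays. The first probe set read 5.60, 5.85 and 6.05 in C and at least 6.93 in all other arrays. Loss of Trp53inp2 alone is argued against only by the value of 1.67 in Wt minus C, where neither group carries the ablation, and a single faulty probe set only by the pair. Both are among the values that drew attention to the gene, so neither is a separate test. A further probe set, too dim for the filter, adds little, with 3.73 at most in C and 3.86 at least elsewhere, and whether the probe sets share sequence is not given. A small difference of the C animals at many genes stays open: 244 other probe sets had all C arrays below or all above the rest, by any gap. The median of the other trios of arrays was 76, but 40 of 286 trios had as many and the highest other had 4874. By a gap of at least 0.5 there were 0 such probe sets of 22516, and up to 17 for another trio. The gaps of the Wdfy1 pair were 0.88 and 0.96, so no other probe set past the filter set the C arrays apart as far. A difference at a single locus also stays open, untested here. A second probe set of Rab4a, also outside the gene tests, was higher by 1.08 in Wt minus C.

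Trp53inp2 was not higher in SKM-Tg than in Wt. Saturation at the top of the array's range is argued against, because the brightest probe set lay at least 1.89 above Trp53inp2 in every SKM-Tg array. That distance cannot show whether this probe set itself levels off at a lower signal, which stays open. A probe set that does not read the transgene stays open and may account for the pattern, since the gene has 1 probe set here and its position relative to the transgene is not given. That the SKM-Tg muscles carry no more Trp53inp2 transcript than Wt stays open as well and was not tested.

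The arrays of the Tg line spread more than those of the KO line, 2.06 times by the median SD. An effect of the transgene as the sole cause is argued against, because component 1 ranged over 68.3 within Wt alone and over 32.9 within SKM-Tg. Nonspecific hybridisation of GC-rich probes may be part of it. Its control signal had a Pearson r of 0.925 with component 1 (exact permutation p 0.0103, adjusted 0.0825 over 8 p-values) and a Spearman rho of 0.821 (exact permutation p 0.0341, adjusted 0.137) over 7 arrays; without Wt 2 and SKM-Tg 3 r was 0.549, so the relation rests in part on them, and with this signal in the fit the spread ratio was 1.45. Fat in the dissected muscle also stays open, with r 0.431 for Adipoq (exact permutation p 0.317, adjusted 0.406), rho 0.429 (p 0.354, adjusted 0.406), r 0.148 without Wt 1 and Wt 3, and a ratio of 1.75 with Adipoq in the fit.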

How the results depend on the processing

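Alternatives with the GC-rich control signal or a block were chosen after seeing the data, all others before. The labels give no shared replicate numbers, litters or days. Mice of C and SKM-KO with neighbouring numbers were tried as a block. Deviations from group means correlated at 0.459, 0.0645 and 0.231 within pairs. Of 6 arrays, 4 correlated best with their own pair, a hint and no pairing. The block left 1 gene and 8 lists called in SKM-KO minus C and 1 gene in the difference of effects. With 1 array left out of a group of 3, the fit still pools the spread of all groups. Signals near the filter, such as that of H3c11, lie close to background, which limits how small a change can be seen.

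Trp53inp2 in SKM-KO minus C kept its direction and call under every alternative run, from -2.45 to -2.24 with single arrays left out. The correlation of the effects then ran from -0.0753 to 0.0336, so its sign is not settled. Most of 141 other named results had no call to lose, so their total says little about the calls. Of their 3394 settings, 3249 kept direction and side of the threshold, 79 lost a call, 57 gained one and 9 reversed.

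Trp53inp2 in SKM-Tg minus Wt, -0.06 without a call, reversed to 0.074 with the GC-rich control signal as a covariate and to 0.027 without both arrays highest in it. It ran from -0.17 without Wt 3 to 0.06 without Wt 2. Lipe in SKM-Tg minus Wt, -0.14, reversed to 0.038 with array weights, 0.14 with the covariate and 0.030 without both arrays, and ran from -0.31 without Wt 3 to 0.12 without Wt 2. In SKM-KO minus C, with single arrays left out, Errfi1 ran from -0.0057 without C 1 to 0.39 without C 2, and Mt1 from -0.0021 without C 1 to 0.64 without C 3. Adipoq ran from -0.61 without SKM-KO 2 to 1.25 without SKM-KO 3, and Scd1 from -0.66 to 1.17 without the same arrays. The macrophage list ran from an adjusted p of 1.48e-04 without C 1 to one of 0.959, reversed, without C 3.

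For genes changed in SKM-KO minus C, the count of 1 became 2 with the mean of a gene's probe sets and 3 over all probe sets; it was 1 without each array in turn. For SKM-Tg minus Wt, the limma count of 0 (717 at an unadjusted p under 0.05) became 1487 with array weights, which ran from 0.147 for Wt 2 to 7.23 for Wt 1; it ran from 0 to 30 with single arrays left out, 30 without Wt 3. For the difference of effects, the count of 2 became 1 with median centring, the 75th percentile filter, all probe sets and both arrays out, and 227 with array weights; with single arrays left out it was 1 to 2, and 2 only without Wt 3, where Cbr2 (adjusted p 0.0167) took the place of H3c11. H3c11 there had an adjusted p of 0.0766 with median centring and 0.0547 to 0.25 with single arrays left out.

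For Wt minus C, the count of 1 became 0 by limma with quantile normalization (2927 at an unadjusted p under 0.05), cyclic loess (2905), no filter (3484), a separate fit (1391), the covariate (654) and both arrays out (1302), 2 with the mean of probe sets, 4 over all probe sets and 5787 with array weights. It was 4119 without Wt 3 and 0 without each other array.

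For lists called in SKM-KO minus C, 7 became 0 with an estimated correlation and with fry; with single arrays left out it ran from 6 to 13, with 13 without C 1 and 11 without C 2. Its lysosome list kept its call without each array (adjusted p up to 0.0359). With array weights the glucocorticoid, atrophy, oxidation and glycolysis lists lost their calls (0.281, 0.369, 0.369 and 0.220), and with the 75th percentile filter the macrophage list (0.989). For lists in SKM-Tg minus Wt, 1 became 0 with quantile normalization, an estimated correlation and fry, 2 with the 75th percentile filter, 4 with the mean of probe sets and a separate fit, 5 with no filter, array weights and the covariate, and 7 with both arrays out. With single arrays left out it was 0 without Wt 1, Wt 3 or SKM-Tg 3, 2 without C 1, 3 without SKM-KO 2, SKM-Tg 1 or SKM-Tg 2, and 7 without Wt 2 or SKM-Tg 4. Its lysosome list lost its call with quantile normalization (0.0886) and the covariate (0.0527). In the difference of effects, the unfolded protein response list lost its call without C 1, SKM-KO 3, Wt 3 or SKM-Tg 3 (adjusted p 0.240, 0.114, 0.326 and 0.0587) and with array weights (0.121). The immediate early list lost its call without C 3, SKM-KO 1, Wt 2, Wt 3 or SKM-Tg 3 (0.123, 0.0943, 0.459, 0.0639 and 0.168), and with the 75th percentile filter, the mean of probe sets, array weights, the covariate and both arrays out (0.0975, 0.0695, 0.690, 0.481 and 0.572), while the lysosome list kept its call without each array (up to 0.0335).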

Other observations

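The lists of liver transcripts and imprinted genes below were chosen only after values of their members were seen, so their counts and medians are given without a test.

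Transcripts made mainly by the liver had a median of -0.52 in SKM-KO minus C, with 9 of 10 measured members negative. Alb, the main plasma protein, stood at -2.23, Apoa1, the main protein of high-density lipoprotein, at -1.03, and Ttr, the carrier of thyroxine, at -0.76. Within C the level varied: Alb read 8.67 in C 2, 7.22 in C 1 and 5.37 in C 3. In the Tg line, Alb read 7.02 in SKM-Tg 4, 7.0 in Wt 1 and 6.29 in SKM-Tg 2. The list in SKM-Tg minus Wt had 7 of 10 members positive, with a median of 0.12.

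Of imprinted genes, 9 of 15 measured members were positive in SKM-KO minus C (median 0.13) and 12 of 15 in SKM-Tg minus Wt (median 0.09). Usp29, a paternally expressed gene, read 4.96, 4.80 and 5.04 in C and 5.37, 5.25 and 5.28 in SKM-KO. Its signals in Wt, 5.28, 5.13 and 5.29, also lay above all C arrays. All these signals lay near the filter, and another Usp29 probe set, too dim for it, differed by 0.01 in SKM-KO minus C. Peg3, the neighbour of Usp29 in the same imprinted domain, had signals of at least 8.25 in SKM-KO and of 7.38, 7.29 and 8.0 in C 1, C 2 and C 3. Its signals in Wt, 6.93, 5.33 and 8.51, reached from below all C arrays to above all SKM-KO arrays.

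Nnt, the mitochondrial nicotinamide nucleotide transhydrogenase, which is deleted in part in some C57BL substrains, read 9.03 in C 1 and at least 10.29 in every other array. The hybridisation control signal was highest in SKM-Tg 4, at 10.4.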
